A study of Mus musculus with 48 samples.

How the data were processed

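The deposited values are estimated counts and TPM per transcript from Salmon, per the file headers, in 1 table for each of the 48 libraries. Per the submitters' processing notes, reads were quantified against a GRCm38 transcriptome; the Salmon version is not given. Per the labels' protocols, RNA came from a blood RNA kit, globin and ribosomal RNA were depleted, and libraries were stranded. Whether the quantification used the strand is not stated, so antisense and overlapping genes are uncertain. A series-level length table was deposited as well, and its 12 columns match no sample name and were not used. The deposited TPM were not used beyond a check of the unit.

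The tables list 109617 transcripts, of which 108214 (98.7%) matched the GENCODE vM21 annotation, and the unmatched ones took 0.155 to 0.354% of a library's reads. Estimated counts were summed to 45321 genes and rounded to whole numbers. Gene positions are those of GRCm38. Within each group all 28 pairs of libraries differed, with a lowest chi-square of 14.9 per degree of freedom.

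The main model was chosen before the data were examined. It was edgeR's quasi-likelihood fit of all 48 libraries with 1 coefficient per group, TMM scaling and edgeR's expression filter by group, which left 14802 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by TMM unless said otherwise. "Tumour" is the equally weighted mean of the 4 tumour groups. Each mouse is 1 library and the unit of replication. Names of groups follow the labels.

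Genes named in the text follow a rule set before the data were examined. In 6 comparisons they are the 6 with the largest positive and the 6 with the largest negative log2 fold change among called genes averaging at least 5 CPM, without immunoglobulin and T cell receptor segments and genes with provisional symbols or none. To these come up to 4 members with the smallest p of each list described, and 3 per direction for each genotype against healthy blood. Which lists to describe was chosen after the values were seen. The text gives the genes that matter most among these, and says where a gene falls outside the rule.

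There were 32 gene lists fixed before the data were examined, and 29 had enough tested members. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists within a comparison, and are those the results describe before the closing section. Of 129 camera calls over 11 comparisons, 0 held with an estimated correlation. Those calls describe a ranking of genes in these libraries. Another 7 lists were added after seeing the data: hepatocyte, liver macrophage and sinusoidal endothelium, tissue macrophage, glucocorticoid target, mast cell, thymocyte and lymphoid precursor, and rRNA-derived. The score of a list is its mean log2 CPM (prior count 2) per library. Numbers of libraries or mice said to be higher or lower are those above or below the median of the comparison group. Scores were compared by 2-sided exact permutation tests, or with 100000 resamples where 32 libraries faced 8, adjusted over 290 tests, of which 69 were called. With the share of counts in place of the score 102 were called.

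Counts were simulated with 200 changed genes among 14802, beside a further list of genes raised 1.5-fold. The fit for KP against healthy recovered 40, 96, 100 and 90% of changes of 1.5-, 2-, 4- and 0.5-fold, with 4.84% false calls. For cerulein against healthy the shares were 54, 92, 100 and 94%, with 9.85% false calls. For KP Cdkn2a Smad4 against KP they were 72, 96, 100 and 94%, with 3.05% false calls. All groups were simulated from common means and a common dispersion trend, without outlying libraries, so these rates need not hold for the real groups.

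Alternatives planned beforehand were DESeq2, RLE scaling, limma-voom with sample weights, nearly no filter on low counts, a stricter filter, a fit of only the groups compared, a replicate block, a gene length offset from the deposited effective lengths, abundant genes left out, and a fold threshold. Every library was also left out in turn. Leaving out cerulein replicates 4, 6 and 7, leaving out the 4 libraries with the lowest TMM factors, and testing protein-coding genes only were added after seeing the data. Each count of called genes was compared with 26 splits of the same libraries, the real one included. An earlier run drew slightly more splits, and was shortened to keep the run time down. It put every count on the same side of the threshold. Single highest values differed, and the share of splits for KP Smad4 against KP was more than 2 times as large, so shares from so few splits are rough.

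Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.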

Results

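The series measured total RNA in whole blood of C57BL/6 mice, to follow what a growing pancreatic tumour does to circulating transcripts. There were 48 libraries in 6 groups of 8 mice. In 4 groups, pancreatic cancer cells were placed in the pancreas and blood was drawn from the heart after 3 weeks. The cells carried mutant Kras and no Trp53 (KP), and some lacked also Cdkn2a (KP Cdkn2a), Smad4 (KP Smad4) or both (KP Cdkn2a Smad4). The healthy group was matched for age. The cerulein group received 6 hourly injections of 80 µg/kg cerulein, a secretagogue peptide that inflames the pancreas, and was bled 2 days after the first dose.

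Depth averaged 34.1 M estimated reads per library (M, mega) and ranged from 25.6 to 45.3 M. Group means were 38.1 ± 4.12 M for KP, 36.2 ± 2.02 for KP Cdkn2a, 35.7 ± 2.97 for KP Smad4, 31.1 ± 2.60 for KP Cdkn2a Smad4, 32.4 ± 3.09 for healthy and 31 ± 3.83 for cerulein (SD, n = 8 each). Protein-coding genes took 64.1% of reads on average (48.7 to 79.3% over libraries). The 7SL RNA of the signal recognition particle took 25.1% (12.6 to 37.0%), and globin transcripts 0.160% (0.0653 to 0.750%). The labels gave a single batch for all 48 libraries, so no comparison could be repeated within batches. Reads mapping to Y-linked genes reached at most 2 counts in any library, and the female transcript Xist averaged 636 to 964 CPM of the library total in the groups.

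The edited genes were looked at first. The knockouts are in the tumour cells, so the transcripts of host blood do not check the labels. Smad4 (chromosome 18, 73639009 to 73703780, GRCm38) stood at 39.9 ± 2.83 CPM in KP Smad4 and 38.5 ± 1.78 in healthy blood (SD, n = 8, TMM-scaled). Its log2 fold change in KP Smad4 against KP was 0.07 (SE 0.05, edgeR adjusted p = 0.676). Kras (chromosome 6, 145216699 to 145250239) was higher in KP Cdkn2a than in healthy blood by 0.38 (SE 0.08, edgeR adjusted p = 0.00193). Trp53 (chromosome 11, 69580359 to 69591873) had a log2 fold change of −0.18 in tumour against healthy blood (SE 0.05, edgeR adjusted p = 0.024). Cdkn2a (chromosome 4, 89274471 to 89294653) was too low to be tested, with group means of 0.0345 to 0.170 CPM of the library total and at most 32 counts in a library.

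**Figure D1:**
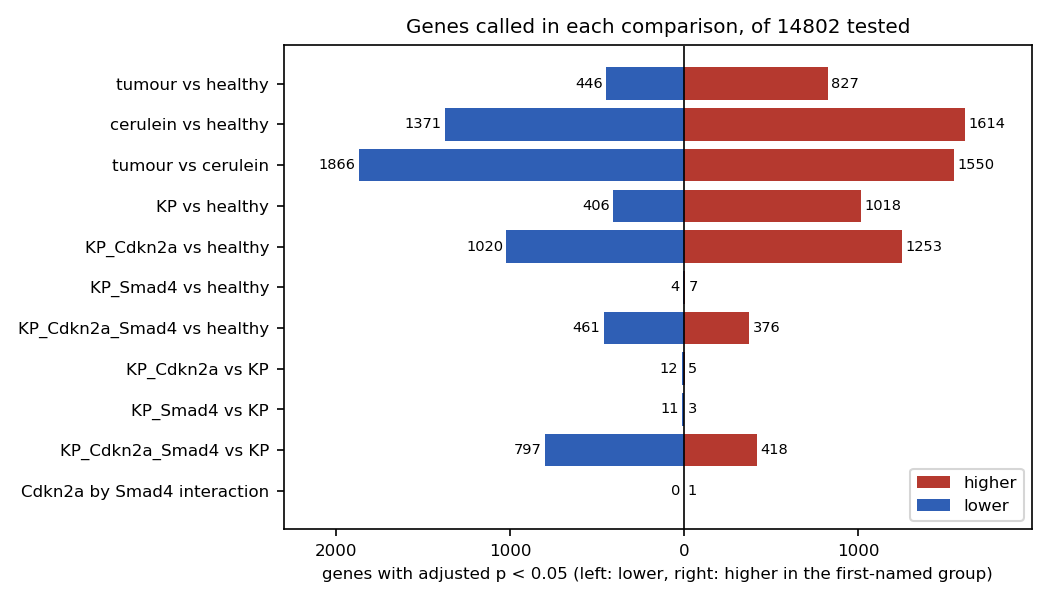
Genes called higher (right) and lower (left) in the first-named group of each comparison, as numbers of genes with an edgeR adjusted p under 0.05 among 14802 tested. KP Smad4 had 11 calls against healthy blood, and cerulein 2985.

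Tumour against healthy blood asked which host transcripts mark a pancreatic tumour whatever its genotype. Blood of tumour-bearing mice held more neutrophil transcripts, from both mature cells and the granule genes of immature ones. Scores of myeloid inflammatory and suppressive lists were higher too, with 10 of 20 and 6 of 17 genes called. The interferon score was slightly higher, and above the healthy median in 28 of 32 mice, while globin transcripts were lower. A group of small nucleolar RNAs was lower in the mean of the tumour groups, but single genotypes had such calls almost only in KP and KP Cdkn2a. No single T cell or B cell gene was called by edgeR.

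In that comparison 1273 genes were called, 827 higher and 446 lower (edgeR, 3767 at an unadjusted p under 0.05), and 810 without healthy replicate 5. Steap4, a metalloreductase of inflamed myeloid cells (chromosome 5, 7960457 to 7982213), rose from 2.97 ± 1.03 CPM (SD, n = 8) to 20.9 ± 12.7 (n = 32), a log2 fold change of 2.75 (SE 0.41, edgeR adjusted p = 6.37e-05), in 32 of 32 tumour libraries. Vcan, which encodes the matrix proteoglycan versican (chromosome 13, 89655312 to 89742509), rose by 2.94 (SE 0.53, edgeR adjusted p = 0.000644), from 4.39 ± 1.84 CPM to 37.7 ± 35.1. Sema6b, a semaphorin (chromosome 17, 56123085 to 56140343), rose by 2.76 (SE 0.49, edgeR adjusted p = 0.000556). Like Steap4, it lay above the healthy median in 32 of 32 tumour libraries. The acute-phase gene Saa3 rose by 3.54, and by 4.46 without healthy replicate 4. The arginase gene Arg1 rose by 6.56 (SE 2.08, edgeR adjusted p = 0.039), from 0.067 to 19 ± 90.3 CPM. Its log2 fold change was 5.21 without KP replicate 1, and the call ended without any 1 of healthy replicates 1, 2, 3, 4, 5, 6, 7 or 8 (adjusted p up to 0.0686). Mboat2, a lysophospholipid acyltransferase gene, fell by 0.91. The signal recognition particle copy Rn7s6 fell by 1.98 (SE 0.26, edgeR adjusted p = 1.49e-05), but shares reads with near-identical copies. Of 63 small nucleolar RNAs tested, 20 were lower. By genotype, 30 were called lower in KP, 29 in KP Cdkn2a, 1 in KP Smad4 and 0 in KP Cdkn2a Smad4.

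The mature neutrophil list had 14 of 16 members higher and 0 lower (15 higher when adjusted over the list alone). Its median log2 fold change was 1.16 (camera adjusted p = 2.63e-16, and adjusted p = 0.157 with an estimated correlation). Its members S100a9 (chromosome 3, 90692632 to 90695721; log2 1.72, SE 0.30), S100a8 (1.78), the chemokine receptor Cxcr2 (1.44) and Hdc (1.49) rose. The list score averaged 4.95 ± 0.65 log2 CPM in tumour (SD, n = 32) and 3.87 ± 0.23 in healthy libraries (n = 8), with 32 of 32 above the healthy median (2-sided permutation test, 100000 resamples, adjusted p = 0.00322). Immature neutrophil granule genes had 11 of 14 higher (11 adjusted over the list alone; median 1.62; camera adjusted p = 2.95e-11, and adjusted p = 0.157 with an estimated correlation), led by Prtn3 (3.33), Lcn2 (2.00) and Mmp8 (1.67).

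Among inflammatory cytokine and NF-kB genes, 10 of 20 were higher (11 adjusted over the list alone), among them Il1b (1.33), Clec4e (1.47) and Socs3 (1.35), and the score was higher in 32 of 32 libraries (difference 0.70, permutation adjusted p = 0.00706). In the suppressive myeloid list 6 of 17 were higher (6 adjusted over the list alone), with Wfdc17 (2.51, SE 0.37, edgeR adjusted p = 6.37e-05), Ifitm1 (2.11) and Arg2 (1.49). Complement and coagulation genes had 6 of 18 higher (11 adjusted over the list alone), with C5ar1 and Itgam, and extracellular matrix and adhesion genes 9 of 21 (9 adjusted over the list alone), with Vcan and Tgfbi. These lists were called by camera (inflammatory adjusted p = 5.41e-07, suppressive 2.35e-05, complement 4e-06, matrix 6.38e-06), and each had adjusted p = 0.171 with an estimated correlation. In the type I interferon response list 6 of 23 were higher and 2 lower (10 and 2 adjusted over the list alone). Its camera adjusted p was 2.22e-05, and adjusted p = 0.24 with an estimated correlation. Oas2 (0.79), Oasl2 (0.78) and Rtp4 (0.58) rose, the lower ones, named after their values were seen, were Cxcl10 (−0.71) and Ifit2 (−0.53), and the score was higher in 28 of 32 libraries (0.24, permutation adjusted p = 0.0476).

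All 4 globin genes tested were lower (4 adjusted over the list alone), and their paralogs share reads. Hbb-bs (chromosome 7, 103826534 to 103828096) fell from 685 ± 779 CPM to 182 ± 123, a log2 fold change of −2.02 (SE 0.32, edgeR adjusted p = 0.000181) that was −1.34 without healthy replicate 5. Without that library Hba-a1 moved from −1.99 to −1.29, and Hba-a2, at −1.02, was no longer called (adjusted p = 0.0841). The globin list's camera adjusted p was 2.35e-05, and adjusted p = 0.157 with an estimated correlation. Lars2, whose annotated locus collects ribosomal RNA reads (chromosome 9, 123366927 to 123462666), fell by 4.12 (SE 0.77, edgeR adjusted p = 0.000971), and by 3.18 without healthy replicate 5. The erythroid list, whose 22 members exclude globins, had 0 called members by edgeR (0 adjusted over the list alone, 7 higher unadjusted; median 0.19; camera adjusted p = 0.122, and adjusted p = 0.814 with an estimated correlation). DESeq2 called 1 of them higher and limma-voom 8. T cell genes had 0 of 19 called by edgeR and DESeq2 (9 lower unadjusted) and 13 lower by limma-voom, with a median of −0.20 (camera adjusted p = 7.79e-06, and adjusted p = 0.38 with an estimated correlation). B cell genes had 0 of 17 called by edgeR and DESeq2 (7 lower unadjusted) and 5 lower by limma-voom, with a median of −0.27 (camera adjusted p = 8.74e-05, and adjusted p = 0.447 with an estimated correlation). Cytosolic ribosomal protein genes had 7 of 40 lower (12 adjusted over the list alone; median −0.11; camera adjusted p = 1.42e-07, and adjusted p = 0.333 with an estimated correlation). The largest among these, Rps12 (−0.36), was not called without healthy replicate 3 (adjusted p = 0.113). The platelet (17 genes, median −0.25) and proliferation (20 genes, median −0.03) lists had 0 calls by edgeR, DESeq2 or limma-voom, with 3 lower and 1 higher unadjusted.

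Cerulein against healthy blood asked what acute pancreatitis does to the same transcripts. The erythroid programme fell, the genes of haem synthesis and the red cell skeleton that young red cells carry. Of the cell-cycle genes 11 of 20 fell, and of the interferon genes 6 of 23. Most immature neutrophil granule genes rose. Hepatocyte genes reached 902, 24800 and 1520 CPM in sum in replicates 4, 6 and 7, and 16.4 in replicate 8. Changes carried by replicates 4, 6 and 7 are given apart.

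Against healthy blood 2985 genes were called in cerulein, 1614 higher and 1371 lower (edgeR, 4679 unadjusted). Without cerulein replicates 4, 6 and 7, a choice made after seeing the data, 1208 were called, 269 higher and 939 lower. Without replicate 6 alone 942 were higher and 1271 lower, and by DESeq2 1486 and 1535. Among tested genes that fit the naming rule, Apoc1, Arg1, Me1, Gnmt, Adh1 and Pklr rose most, with log2 fold changes from 7.05 to 9.03. Hepatocytes transcribe these genes strongly. Without cerulein replicate 6 alone, Apoc1 moved from 9.03 to 5.97, Arg1 from 8.95 to 7.65, Me1 from 8.12 to 4.88, Gnmt from 7.59 to 4.43, Adh1 from 7.50 to 4.09 and Pklr from 7.05 to 4.08. Without all 3, Apoc1 stood at 1.80, Arg1 at 1.48, Gnmt at 0.61, Adh1 at 0.24, Me1 at −0.16 and Pklr at −1.04, none of them called by edgeR (adjusted p from 0.085 to 0.965). Arg1, which myeloid cells transcribe too, did not follow albumin (Alb) between these libraries, at 79.1, 165 and 9.24 CPM in replicates 4, 6 and 7, where Alb stood at 542, 16000 and 859.

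All 22 erythroid genes were lower in cerulein blood (22 adjusted over the list alone; median −1.39; camera adjusted p = 3.61e-22, and adjusted p = 0.325 with an estimated correlation). Without cerulein replicates 4, 6 and 7 there were 14. Alas2, the first enzyme of haem synthesis in red cells (chromosome X, 150547375 to 150570638), fell from 41050 ± 18860 CPM to 12950 ± 2518 (SD, n = 8 each), a log2 fold change of −1.67 (SE 0.20, edgeR adjusted p = 5.05e-07). Bpgm (−1.63), Fech (−1.55) and Hemgn (−1.39) fell too. The erythroid score was 5.89 ± 0.32 log2 CPM in cerulein and 7.17 ± 0.52 in healthy libraries, with 0 of 8 above the healthy median (2-sided exact permutation test, adjusted p = 0.00322). Proliferation genes had 11 of 20 lower (11 adjusted over the list alone; median −0.70; camera adjusted p = 5.7e-08, and adjusted p = 0.454 with an estimated correlation), among them Ccna2 (−1.12), Birc5 (−1.02) and Top2a (−0.84). The score difference was −0.52 (exact permutation adjusted p = 0.00322).

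Isg20, an interferon-induced exonuclease gene (chromosome 7, 78913424 to 78920396), fell from 1864 ± 834 CPM to 545 ± 121, or −1.77 (SE 0.21, edgeR adjusted p = 5.05e-07). Irf7, which drives the interferon response (chromosome 7, 141262706 to 141266481), fell by 1.30 (SE 0.18, edgeR adjusted p = 1.41e-06), from 367 ± 116 CPM to 149 ± 25.7. Rsad2 (−1.57), Isg15 (−1.48) and Ifit1 (−1.04) fell as well. In the type I interferon response list 6 of 23 were lower and 0 higher (6 adjusted over the list alone), while the list median was 0.11 and the mean −0.22 (camera adjusted p = 0.145, and adjusted p = 0.738 with an estimated correlation). Rn7s6 (−2.54), Rn7s2 (−2.07), Apol11b (−1.95) and Fam220a (−1.89) fell. Mir6236, within a ribosomal RNA repeat, fell by 3.00, and its call ended without healthy replicate 5 (−2.14, adjusted p = 0.131). Globins had 3 of 4 lower (4 adjusted over the list alone; median −1.22; camera adjusted p = 0.00293, and adjusted p = 0.454 with an estimated correlation). The call of Hbb-bs (−1.57) ended without healthy replicate 5 (−0.89, adjusted p = 0.144).

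Immature neutrophil granule genes had 10 of 14 higher (12 adjusted over the list alone; median 1.05; camera adjusted p = 5.05e-06, and adjusted p = 0.454 with an estimated correlation), and 8 without cerulein replicates 4, 6 and 7. Prtn3 rose by 3.08. Camp moved from 2.91 to 1.99, and Ltf from 2.53 to 1.81, without cerulein replicate 1. In the mature neutrophil list 1 of 16 was called, the protease inhibitor gene Slpi at 1.06 (1 adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.738 with an estimated correlation). Complement and coagulation genes had 10 of 18 higher (11 adjusted over the list alone; camera adjusted p = 0.000102, and adjusted p = 0.454 with an estimated correlation), but 1 without cerulein replicates 4, 6 and 7. Cfb moved from 4.17 to 2.35, C3 from 2.97 to 1.59 and Cfh from 2.81 to 1.79 without cerulein replicate 6. Fibroblast and endothelial genes had 5 of 9 higher (6 adjusted over the list alone), against 0 higher and 1 lower without the 3 libraries. Mitochondrially encoded genes had 5 of 13 higher (8 adjusted over the list alone), against 1 without them. T cell and B cell lists had 0 calls by edgeR, DESeq2 or limma-voom, with 1 and 0 lower unadjusted. Cytosolic ribosomal protein genes had 13 of 40 lower (14 adjusted over the list alone), with Rplp0 at −0.78, and 8 without the 3 libraries.

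**Figure D2:**
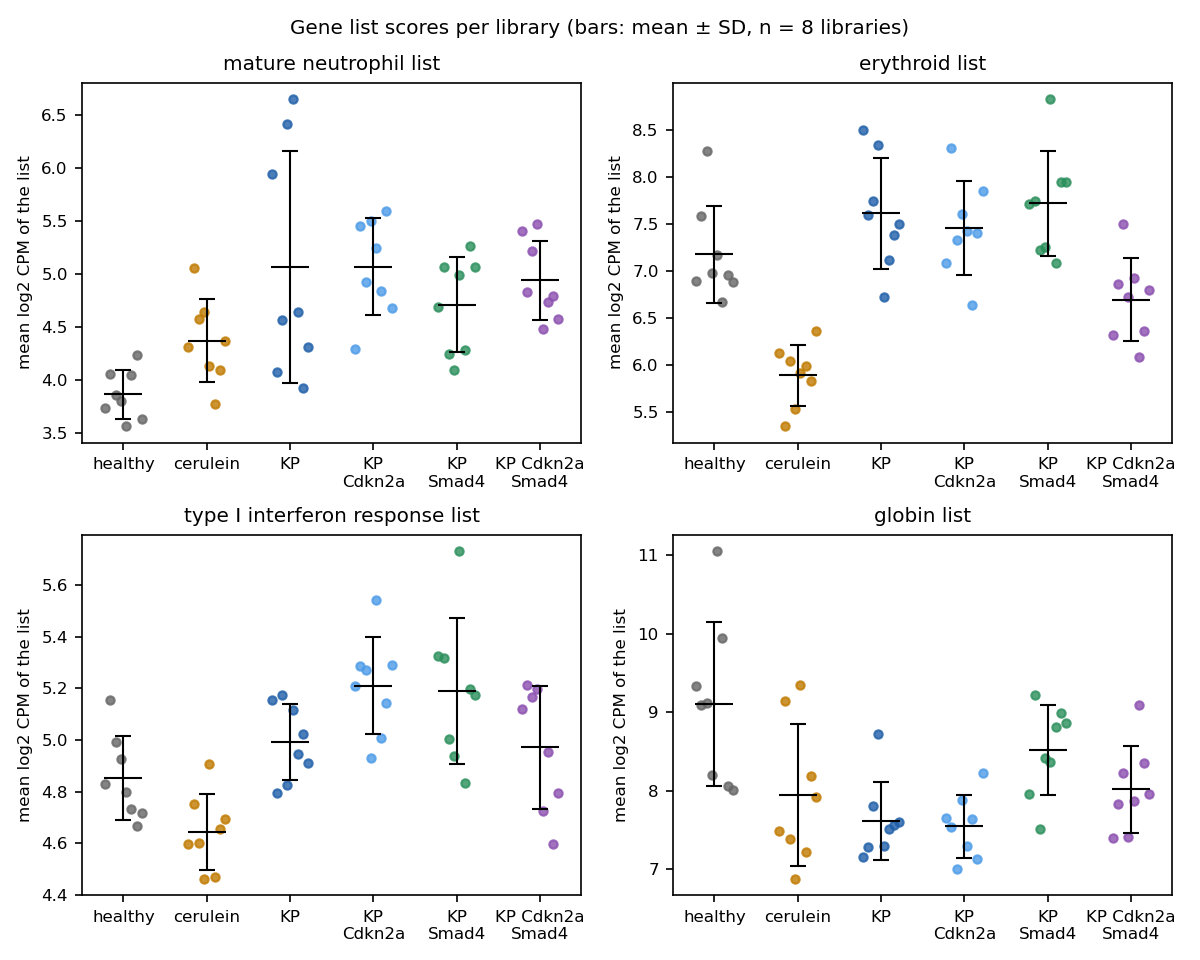
Mean log2 CPM of the mature neutrophil, erythroid, type I interferon response and globin lists in each library (points), with the mean and SD of each group of 8 (bars). All 32 tumour libraries lie above the healthy median in the neutrophil list, and the cerulein libraries average 5.89 in the erythroid list against 7.17 in healthy blood.

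Tumour against cerulein blood asked what separates cancer from inflammation of the same organ. Red cell genes were all called higher, and their score lay above the cerulein median in every tumour library. Of the cell-cycle genes 12 of 20, and of the interferon genes 10 of 23, were higher with tumours than with cerulein. Red cell and cell-cycle genes fell in cerulein against healthy blood, while tumour against healthy blood had no edgeR calls in either list. Against healthy blood, some interferon genes rose with tumours and some fell with cerulein. Without the 3 cerulein libraries highest in hepatocyte genes, no fibroblast or endothelial gene was called.

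Of 3416 genes called, 1550 were higher and 1866 lower in tumour blood (edgeR, 4963 unadjusted). The total was 2221, with 1357 higher and 864 lower, without cerulein replicate 6, and 1295, with 1006 higher and 289 lower, without cerulein replicates 4, 6 and 7. All 22 erythroid genes were higher (22 adjusted over the list alone; median 1.59; camera adjusted p = 1.24e-31, and adjusted p = 0.0812 with an estimated correlation), and 21 without the 3 libraries. Spta1, the alpha chain of red cell spectrin (chromosome 1, 174172776 to 174248450), averaged 1413 ± 653 CPM in tumour (SD, n = 32) and 370 ± 97.6 in cerulein blood (n = 8), or 1.87 (SE 0.22, edgeR adjusted p = 1.41e-08). The membrane genes Add2 (2.48), Tmod1 (2.16), Epb42 (2.15) and Slc4a1 (2.12) were higher, as were Apol10a (2.66, SE 0.41, edgeR adjusted p = 1.91e-06) and Pkd1l1 (2.08). The erythroid score was higher in 32 of 32 libraries, by 1.48 (permutation adjusted p = 0.00145; its raw p of 1e-05 was the smallest that 100000 resamples can give).

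Proliferation genes had 12 of 20 higher (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.42e-10, and adjusted p = 0.433 with an estimated correlation), and 12 without the 3 libraries. In the type I interferon response list 10 of 23 were higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 3.36e-06, and adjusted p = 0.441 with an estimated correlation), against 7 and 1 without the 3 libraries. Irf7 was higher by 1.49 (SE 0.16, edgeR adjusted p = 1.41e-09), Rsad2 by 1.87, Ifit1 by 1.42 and Oasl2 by 1.42. The lower ones, named after their values were seen, were Cxcl10 (−1.08) and Mx1 (−0.37). The score was higher in 31 of 32 (0.45, permutation adjusted p = 0.00193). Mature neutrophil genes had 8 of 16 higher (8 adjusted over the list alone; camera adjusted p = 0.000334, and adjusted p = 0.992 with an estimated correlation), but 1 without the 3 libraries, while the median moved from 0.60 to 0.53. S100a9 was higher by 1.05 and Mxd1 by 1.26. Inflammatory cytokine and NF-kB genes had 4 higher. These were Socs3 (0.96), Trem1 (0.93), Il1b (0.82) and Clec4e (0.79). Without cerulein replicate 6 the adjusted p was 0.0547 for Trem1 and 0.0543 for Il1b, and Clec4e lost its call without cerulein replicates 1, 5, 6, 7 or 8 (adjusted p up to 0.089). Mitochondrially encoded genes had 9 of 13 lower (10 adjusted over the list alone) and fibroblast and endothelial genes 7 of 9, against 1 and 0 without the 3 libraries. The median of the fibroblast and endothelial genes moved from −1.80 to −0.07. Apoh, Adh1, Apoc1, Gnmt, Me1 and Pklr, from −7.91 to −6.58, were the largest falls among tested genes that fit the naming rule. Without cerulein replicate 6 Apoh was at −4.97, Adh1 at −4.09, Apoc1 at −4.24, Gnmt at −3.92, Me1 at −3.36 and Pklr at −3.62. Without all 3, Me1 was at 1.68 and Pklr at 1.49. Of small nucleolar RNAs 44 of 63, and of small nuclear RNAs 20 of 36, were lower in tumour blood.

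Each genotype against healthy blood asked whether the blood response depends on the tumour's genes. Neutrophil scores were above the healthy median in all 8 mice of each genotype. Counts of called genes differed widely, from 11 in KP Smad4 to 2273 in KP Cdkn2a. T cell scores fell in KP and KP Cdkn2a, and interferon scores rose in KP Cdkn2a and KP Smad4. Differences between genotypes in these scores were tested only against KP.

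KP had 1424 calls against healthy blood, 1018 higher and 406 lower (edgeR, 3737 unadjusted), and 613 without KP replicate 1 or 779 without KP replicate 5. A fit of only KP and healthy libraries called 1 gene, and limma-voom 351, 153 higher and 198 lower. KP Cdkn2a had 2273, 1253 higher and 1020 lower (4463 unadjusted), with 1484 without its replicate 2, 1364 without its replicate 7, and 1495 higher and 1552 lower in a fit of only these groups. KP Cdkn2a Smad4 had 837, 376 higher and 461 lower (3314 unadjusted). The balance turned in the fit of only these groups, with 1012 higher and 545 lower, with limma-voom, with 1273 and 897, and without the 4 libraries of lowest TMM factor, with 109 and 34. It also turned without its replicates 1 (47 higher and 44 lower), 4 (14 and 8), 5 (503 and 477), 6 (200 and 187) and 7 (389 and 311), and without healthy replicate 3 (44 and 9). The count of KP Cdkn2a Smad4 was 91 without its replicate 1, 500 without 2, 22 without 4 and 387 without 6, and 53 and 443 without healthy replicates 3 and 5. KP Smad4 had 11, 7 higher and 4 lower (1723 unadjusted, and 48 by DESeq2 or 1155 by limma-voom), led by Steap4. That count fell to 1 without its replicate 7 and rose to 18, 5 higher and 13 lower, without its replicate 8, and was 5, 3 and 3 without its replicates 1, 2 and 5. Leaving out healthy replicate 1, 3, 4, 5, 6, 7 or 8 gave 2, 6, 3, 3, 5, 3 or 2 calls. Without the 4 libraries of lowest TMM factor 2 were higher and 13 lower, and lower calls also outnumbered higher ones without healthy replicates 2 (4 higher and 5 lower) and 6 (2 and 3).

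The mature neutrophil score was higher than in healthy blood by 1.20 in KP (exact permutation adjusted p = 0.0167), 1.20 in KP Cdkn2a (0.00322), 0.84 in KP Smad4 (0.0053) and 1.07 in KP Cdkn2a Smad4 (0.00322), in 8 of 8 mice each. By edgeR 15 of its 16 genes were higher in KP, 13 in KP Cdkn2a, 10 in KP Cdkn2a Smad4 and 0 in KP Smad4 (11 adjusted over the list alone and 12 unadjusted in KP Smad4, and 14 adjusted over the list alone in KP Cdkn2a Smad4). Camera adjusted p was 2.13e-14 in KP, 2.48e-12 in KP Smad4 and 3.4e-12 in KP Cdkn2a Smad4, and adjusted p = 0.163, 0.257 and 0.362 with an estimated correlation. Steap4 rose by 3.33 in KP Cdkn2a (SE 0.46, edgeR adjusted p = 5.64e-05), 2.48 in KP Smad4 (adjusted p = 0.0119) and 2.58 in KP Cdkn2a Smad4 (adjusted p = 0.00654). In KP Smad4 it ended without KP Smad4 replicate 7 (adjusted p = 0.0512). Vcan (3.85) and Wfdc17 (2.90) led in KP Cdkn2a, and the glycoprotein gene Lrg1 (2.50) rose in KP Cdkn2a Smad4. In KP, Arg1 (9.997), Spp1 (5.86) and Dab2 (5.62) led, and all 3 calls ended without KP replicate 1 (4.58, 1.83 and 2.75). Among T cell genes 10 of 19 fell in KP Cdkn2a (15 adjusted over the list alone; median −0.35; camera adjusted p = 5.78e-08, and adjusted p = 0.255 with an estimated correlation) and 2 in KP, Lck (−0.33) and Cd5 (−0.47), named after their values were seen. The interferon score rose by 0.36 in KP Cdkn2a (exact permutation adjusted p = 0.0167) and 0.34 in KP Smad4 (0.0395), in 8 of 8 mice each. Plasma cell (−0.44, exact permutation adjusted p = 0.00615) and MHC class II (−0.33, 0.0225) scores fell in KP Cdkn2a, with 0 of 8 mice above the healthy median. The globin score fell by 1.48 in KP and 1.56 in KP Cdkn2a.

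KP and KP Cdkn2a shared 610 higher and 255 lower calls against healthy blood. Independent lists would share 86.2 and 28, and unchanged groups simulated against the same controls 0 and 0. The simulation had no changed genes, so its 0 cannot show how much shared controls add where genes are called. The real groups with the healthy libraries split between them shared 48 and 8. There KP and KP Cdkn2a had only 80 and 548 higher calls, and 26 and 417 lower calls, so fewer could be shared. KP and KP Cdkn2a Smad4 shared 269 and 22 (independent 25.9 and 12.6, simulated 0 and 0). KP Cdkn2a and KP Cdkn2a Smad4 shared 312 and 177 (independent 31.8 and 31.8, simulated 0 and 0). With split controls KP Cdkn2a Smad4 had 0 calls, so those overlaps could only be 0 there. KP Cdkn2a and cerulein shared 396 higher and 228 lower (independent 136.6 and 94.5, simulated 0 and 0, split 29 and 127), with 16 and 3 in opposite directions. In the split fits KP Cdkn2a and cerulein had 444 and 625 higher calls, and 684 and 603 lower calls. Shared higher calls fell there from 396 to 29, further than the lower ones, from 228 to 127. All of these lists were shorter in the split fits, and no independent expectation was set beside the split overlaps. How much the shared controls added to the higher overlap with cerulein therefore cannot be told. Without cerulein replicates 4, 6 and 7 these 2 groups shared 155 higher and 154 lower (independent 23.9 and 73.9).

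Knockout tumours against KP tumours asked what the loss of Cdkn2a, Smad4 or both adds. Loss of either gene alone gave few calls in blood, which changed with single libraries and with the tool. With loss of both, red cell genes were lower than in KP, as were 6 of 20 cell-cycle genes. Of small nucleolar RNAs 30 of 63, and of small nuclear RNAs 14 of 36, were called higher than in KP. Against healthy blood, however, 30 small nucleolar RNAs were lower in KP and 0 were called in KP Cdkn2a Smad4. Of monocyte genes 5 of 16, and of antigen-presentation genes 5 of 19, were called higher.

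KP Cdkn2a differed from KP in 17 genes, 5 higher and 12 lower (edgeR, 1449 unadjusted; 87 by DESeq2 and 1379 by limma-voom, 896 higher and 483 lower). The count was 0 in a fit of only these groups, and 0 without KP Cdkn2a replicate 3 or 5. It was between 4 and 9 without KP replicate 1 or 2 or KP Cdkn2a replicate 1, 2, 4, 6 or 7. It was 44, 103, 125, 57 and 27 without KP replicates 3, 5, 6, 7 and 8, and the balance turned without KP replicate 5, with 60 higher and 43 lower, and without KP Cdkn2a replicates 6, with 5 and 3, and 8, with 11 and 9. The integrin gene Itgax of dendritic cells and macrophages (chromosome 7, 128129547 to 128150657) was higher, at 49.1 ± 13.1 CPM against 29 ± 10.1 (SD, n = 8 each; log2 0.76, SE 0.16, edgeR adjusted p = 0.0317). Its call ended without KP replicates 1 or 2 or KP Cdkn2a replicates 2, 3, 4, 5 or 7 (adjusted p up to 0.0953). Fkbp5, a glucocorticoid-induced chaperone gene (chromosome 17, 28399094 to 28517527), had a log2 fold change of −1.59 (SE 0.31, edgeR adjusted p = 0.0235), at 11.7 ± 1.48 CPM against 35.3 ± 36.4, and lost its call without KP replicates 1 or 4 or KP Cdkn2a replicates 3 or 5 (adjusted p up to 0.0868). Serpine1 was at −5.23, and at 0.15 without KP replicate 1. In the monocyte list 0 of 16 were called by edgeR, 1 higher by DESeq2 and 7 by limma-voom (9 higher and 1 lower adjusted over the list alone, 10 and 2 unadjusted), with a median of 0.50 (camera adjusted p = 8.2e-12, and adjusted p = 0.113 with an estimated correlation) that was 0.38 without KP replicate 1. Among NK and cytotoxic cell genes 0 of 15 were called by edgeR and DESeq2 and 1 by limma-voom (10 higher adjusted over the list alone, 10 unadjusted; median 0.47; camera adjusted p = 1.73e-14, and adjusted p = 0.175 with an estimated correlation). KP replicate 1 had the lowest NK score of its group, and without it the median was 0.35 (camera adjusted p = 7.08e-09, and adjusted p = 0.502 with an estimated correlation). The NK score difference of 0.54, with 8 of 8 mice above the KP median, did not pass correction (exact permutation adjusted p = 0.0711).

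KP Smad4 differed from KP in 14 genes, 3 higher and 11 lower (edgeR, 1732 unadjusted; 75 by DESeq2 and 0 by limma-voom), and in 0 without KP replicate 1. The count was 0 in a fit of only these groups, 9 without KP replicate 4, and 26, 36, 27, 98 and 37 without KP replicates 2, 3, 6, 7 and 8. It was between 6 and 9 without KP Smad4 replicate 1, 2, 3, 4, 6, 7 or 8. The ribosome-assembly gene Nop53 was higher by 0.31 (SE 0.06, edgeR adjusted p = 0.0131). The secreted-protein gene Crispld2 (chromosome 8, 119992438 to 120052793) and the decoy receptor Il1r2 (chromosome 1, 40074079 to 40125231) were lower, at −3.03 each (edgeR adjusted p = 0.0124 each). Without KP replicate 1 the adjusted p was 0.0717 for Nop53, 0.0721 for Crispld2 and 0.148 for Il1r2. Crispld2 averaged 1.77 ± 0.512 CPM in KP Smad4 and 14.4 ± 19 in KP. In the mature neutrophil list 1 of 16 was lower, Il1r2 (4 adjusted over the list alone; camera adjusted p = 0.00145, and adjusted p = 0.468 with an estimated correlation). The globin score was higher in KP Smad4 by 0.90, in 7 of 8 mice (exact permutation adjusted p = 0.0338). Lars2, which followed globins within groups, was also at a median of 426 CPM in KP Smad4 and 9.18 in KP.

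KP Cdkn2a Smad4 differed from KP in 1215 genes, 418 higher and 797 lower (edgeR, 3495 unadjusted). The count was 693 without KP replicate 1, 385 without KP replicate 4, and 596, 537 and 698 without KP Cdkn2a Smad4 replicates 1, 6 and 7. In the erythroid list 20 of 22 were lower (21 adjusted over the list alone; median −1.04; camera adjusted p = 1.74e-17, and adjusted p = 0.63 with an estimated correlation), and 8 without KP replicate 1. Spta1 fell by 1.04, Rhag by 1.23 and Tfrc by 0.87. The score was lower by 0.92 (exact permutation adjusted p = 0.0259), with 8 of 8 mice below the KP median. Proliferation genes had 6 of 20 lower (10 adjusted over the list alone; camera adjusted p = 7.98e-06, and adjusted p = 0.63 with an estimated correlation), and 4 without KP replicate 1. Of 63 small nucleolar RNAs 30, and of small nuclear RNAs 14, were higher. Snord17 (chromosome 2, 144265979 to 144266216) was at 48.4 ± 4.47 CPM against 25.3 ± 3.92 in KP, or 0.94 higher (SE 0.18, edgeR adjusted p = 0.00973), and healthy blood at 47.1 ± 7.36. Against healthy blood 30 small nucleolar RNAs were lower in KP and 0 were called in KP Cdkn2a Smad4 by edgeR. Reads overlapping ribosomal RNA took 6.17 ± 0.907% in KP, 9.47 ± 1.16% in KP Cdkn2a Smad4 and 8.84 ± 2.51% in healthy libraries (SD, n = 8 each). Depth differed too, with means of 38.1, 31.1 and 32.4 M. For the small RNAs, an effect of genotype therefore cannot be told from a difference in library preparation. Monocyte genes had 5 of 16 higher (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000627, and adjusted p = 0.63 with an estimated correlation), with Spn at 0.53, and 3 without KP replicate 1. Ace (0.82) lost its call without KP replicate 4 or KP Cdkn2a Smad4 replicates 1 or 6 (adjusted p up to 0.0592). Among MHC class I and interferon gamma genes 5 of 19 were higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00122, and adjusted p = 0.63 with an estimated correlation). The immunoproteasome genes Psmb9 (0.36) and Psmb8 (0.32) and the peptide transporter gene Tap1 (0.34) rose, Gbp7 fell by 0.47, and 3 were higher without KP replicate 1. Crispld2 fell by 2.86. Mrc1 (−3.75), Stab1 (−3.41) and Asns (−2.94) were not called without KP replicate 1 (−0.76, −1.07 and −1.37), nor Rag1 (−3.75) without KP replicate 2 (0.85).

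The interaction of both knockouts, which asks whether their joint effect differs from the sum, gave 1 gene (edgeR, 1398 unadjusted; 54 by DESeq2 and 185 by limma-voom). Gm25117, a small nucleolar RNA (chromosome 10, 111481493 to 111481636) named after its values were seen, had an interaction of 2.20 (SE 0.41, edgeR adjusted p = 0.0483) at mean levels of 0.146 to 0.559 CPM in the 4 genotypes. The count was 7, 2, 3, 10, 2 and 2 without KP replicates 3 and 7, KP Cdkn2a replicate 6, KP Smad4 replicate 8 and KP Cdkn2a Smad4 replicates 1 and 5. It was 0 without KP replicate 2, 5 or 6, KP Cdkn2a replicate 1, 2, 3, 4, 7 or 8, KP Smad4 replicate 1, 2, 4, 5, 6 or 7, or KP Cdkn2a Smad4 replicate 2, 3, 4, 6, 7 or 8. A test of any difference among the 4 tumour genotypes called 1569 genes (edgeR, 4025 unadjusted). The count was 794, 754 and 940 without KP Cdkn2a Smad4 replicates 1, 6 and 7. Crispld2 led it (adjusted p = 0.000354), followed by Fkbp5, Il1r2 and Bmt2 (each 0.000916). The first 3 stood apart only in KP replicates 1, 4 and 5, and their KP medians of 1.89, 12.8 and 3.54 CPM lay near those of KP Smad4 (1.78, 10.8 and 2.95) and KP Cdkn2a (2.02, 11.7 and 4.95). Bmt2, which encodes a nutrient-signalling methyltransferase, was highest in KP Cdkn2a, at 14.5 ± 0.729 CPM against 10.6 ± 1.10 in KP Smad4 (SD, n = 8 each).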

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

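The tests of the patterns weighed here, and the comparison of called genes with other splits of the libraries, were chosen after the results were seen.

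Liver transcripts stood out in 3 cerulein libraries. Their summed CPM over the 20 genes of the hepatocyte list was 902 in replicate 4, 24800 in replicate 6 and 1520 in replicate 7, or 0.133, 2.93 and 0.2% of counts, against at most 2.53 in the 40 libraries outside the cerulein group. Albumin (Alb) reached 542, 16000 and 859 CPM. Between any 2 of the 3 libraries, log2 CPM over the list correlated across genes, which are not independent replicates, with a Pearson r of at least 0.94 and up to 0.98, so that RNA of liver cells may be in these libraries. Of the 8 cerulein libraries 4 lay above all others, replicate 8 at 16.4, and replicates 1, 2, 3 and 5 at 1.24, 1.31, 1.34 and 1.09, which argues against an effect of cerulein on every treated mouse. An effect in some treated mice stays open, and whether liver tissue came with the heart blood was not tested.

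Globin transcripts were lower in tumour than in healthy libraries. The median log2 fold change of the globin genes was −1.51 (−2.02 to −0.90), while that of the erythroid genes was 0.187 (−0.27 to 0.81), which argues against fewer red blood cell transcripts. Within groups, globin scores followed the rRNA-derived scores over 48 libraries (Pearson r = 0.85, Spearman rho = 0.81, permutation p = 1e-05 each, the smallest possible, adjusted 2e-05 over 4 relations; r = 0.81 without the 2 farthest; 0.46 to 0.97 in single groups), so uneven removal of both RNAs in library preparation is a candidate explanation. Lars2 followed globins as well (r = 0.82, rho = 0.78, p = 1e-05 each; 0.80 without the 2 farthest; −0.03 to 0.94 in single groups). Erythroid scores followed neither globin (r = 0.05, p = 0.733; rho = 0.07, p = 0.648) nor rRNA-derived scores (r = −0.10, p = 0.516; rho = −0.09, p = 0.522). The rRNA-derived list had only 2 tested genes. Reads overlapping ribosomal RNA, a wider measure, averaged 8.84% in healthy libraries and globins 0.273%. Both means were lower in KP, KP Cdkn2a and KP Smad4. In cerulein (11.4 and 0.185%) and KP Cdkn2a Smad4 (9.47 and 0.161%) only globins were lower, so group means do not settle the explanation.

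The interaction of the Cdkn2a and Smad4 knockouts differed from 0 for the small nucleolar RNA Gm25117 (2.20), the 1 gene called by that test.

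Single libraries lay far from the other 7 of their group in 18 of 174 sets of list scores (8.7 expected) and 24 of 306 sets of gene values (15.3 expected). A library counted when its gap to the nearest other took a share of the group's range above Dixon's 95% critical value, which chance gives in about 1 in 20 groups. The genes were those named for the largest fold changes in these same libraries, so that rate need not hold for them. Healthy replicate 3 was highest in cytosolic ribosomal protein (gap 0.698), proliferation (0.635), platelet (0.598), suppressive myeloid (0.533) and glycolysis (0.527) scores, and in Mboat2 (0.585), Rras (0.569) and Fam220a (0.527). KP replicate 1 was highest in epithelial and ductal tumour (0.589) and TGF-beta response (0.561) scores, in Pklr (0.723) and in Mrc1 (0.565). It was lowest in NK and cytotoxic cell scores (0.537), Mboat2 (0.783), Cd300e (0.718) and Ace (0.714). KP replicate 4 was highest in the globin score (0.588), Hba-a2 (0.78), Snora74a (0.74) and CT010467.1 (0.643), and lowest in the eosinophil and basophil score (0.621). KP replicate 2 was highest in Rag1 (0.61), and KP replicate 5 lowest in mitochondrially encoded genes (0.646). Cerulein replicate 6 was highest in mitochondrially encoded genes (0.739) and Neb (0.593), and lowest in eosinophil and basophil genes (0.545). Cerulein replicate 4 was highest in immediate early (0.552) and inflammatory (0.529) scores, and cerulein replicate 8 lowest in Rnu2-10 (0.539). KP Smad4 replicate 8 was highest in Nop53 (0.704), Snord17 (0.662) and Snora74a (0.541). KP Smad4 replicate 2 was highest in plasma cell (0.726), replicate 4 in T cell exhaustion (0.543) scores and replicate 7 in Rag1 (0.529). KP Cdkn2a Smad4 replicates 2, 3 and 7 were lowest in mitochondrially encoded genes (0.558), Adh1 (0.637) and Vcan (0.571). KP Cdkn2a replicate 4 was highest in Me1 (0.567), and replicates 5 and 2 lowest in Rnu2-10 (0.726) and Rnu1a1 (0.563). Healthy replicate 6 was lowest in Cd300e (0.571).

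Each count of called genes was set against 26 splits of the same libraries. In the fit used, only the real split (1 of 26) reached its count for 10 of the 12 counts. That is the smallest share 26 splits can give, and it was not adjusted over the 12 counts, so it does not exclude chance. The fold threshold was left out of what follows, since the splits had none, and with it tumour against healthy had 249 calls. For 5 of the 10, every other fit and every fit without single libraries also stayed above the highest other split, though splits were drawn for the fit used alone. The real count, the highest other and the lowest of these fits were 1273, 346 and 810 for tumour against healthy, 2985, 410 and 1208 for cerulein against healthy, and 3416, 661 and 1295 for tumour against cerulein. They were 837, 1 and 22 for KP Cdkn2a Smad4 against healthy, and 11, 0 and 1 for KP Smad4 against healthy. For KP Smad4 a single call is enough to stay above 0, so this says little about how stable its count is. For the other 5, some fit did not stay above it, so the result holds for the fit used alone. These had 1424, 1011 and 1 for KP against healthy, not above in 4 of 28 fits, 2273, 1497 and 1364 for KP Cdkn2a against healthy, in 2 of 28, and 1215, 453 and 385 for KP Cdkn2a Smad4 against KP, in 1 of 28. Any difference among genotypes had 1569, 867 and 754, in 2 of 44, and the interaction 1, 0 and 0, in 27 of 44. With 1 gene against 0, the interaction could not be told from chance. For KP Cdkn2a against KP, 4 of 26 splits called at least its 17 genes, and the highest other called 2768. For KP Smad4 against KP, 3 of 26 called at least its 14, and the highest other 384. These 2 counts were not set apart from other splits. What made single splits call many times the real count was not tested.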

How the results depend on the processing

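Leaving out cerulein replicates 4, 6 and 7 or the 4 libraries of lowest TMM factor, and protein-coding genes only, were tests chosen after seeing the data. Settings not given for a comparison kept its count within 1.5 times, the cause was not tested except where fewer genes or libraries entered, and DESeq2, RLE, length offset and the setting without abundant genes kept 265, 277, 268 of 278 and 256 of 256 named genes in direction and on their side of the threshold. Among the others, limma-voom kept 202, nearly no filter 255, the replicate block 248 and the 4 libraries left out 254 of 278. Fits of only the groups compared kept 220 of 264, the stricter filter 227 of 229 and protein-coding genes 265 of 267. Leaving out the 3 cerulein libraries kept 235 of 278. Of 104 counts of list members, 29 moved over 1.5 times with limma-voom, 18 in fits of only the groups compared, 15 without the 3 cerulein libraries and at most 10 elsewhere. With limma-voom tumour against healthy had 2950 calls, KP 351, KP Cdkn2a 5190, KP Smad4 1155 and KP Cdkn2a Smad4 2170, each against healthy. Against KP it gave 1379 for KP Cdkn2a, 0 for KP Smad4 and 2249 for KP Cdkn2a Smad4, with 185 for the interaction and 4249 for any genotype difference. At an absolute log2 fold change of at least 1 there were 249 for tumour against healthy, 1048 for cerulein against healthy and 901 for tumour against cerulein. KP then had 565, KP Cdkn2a 416 and KP Cdkn2a Smad4 162 against healthy, and KP Cdkn2a Smad4 205 against KP. Without cerulein replicates 4, 6 and 7 there were 1208 for cerulein against healthy, 1295 for tumour against cerulein, 3 for KP Smad4 against healthy, 43 for KP Cdkn2a and 32 for KP Smad4 against KP, and 2 for the interaction. In fits of only the groups compared KP had 1 call, KP Smad4 243 and KP Cdkn2a Smad4 1557 against healthy. KP Cdkn2a had 0, KP Smad4 0 and KP Cdkn2a Smad4 586 against KP, the interaction 0 and any difference 981. DESeq2 gave 48 for KP Smad4 and 1313 for KP Cdkn2a Smad4 against healthy, 87 for KP Cdkn2a and 75 for KP Smad4 against KP, and 54 for the interaction. With nearly no filter (25009 genes) there were 3 for KP Smad4 and 464 for KP Cdkn2a Smad4 against healthy, 2 for KP Cdkn2a and 6 for KP Smad4 against KP, and 0 for the interaction. The stricter filter (9159 genes) gave 1 for KP Smad4 against healthy, 7 for KP Cdkn2a and 3 for KP Smad4 against KP, and 0 for the interaction. The length offset gave 6 for KP Smad4 against healthy and 0 for the interaction, and protein-coding genes only gave 2 and 0. Without the 4 libraries of lowest TMM factor KP Cdkn2a Smad4 had 143 against healthy, KP Smad4 1 against KP and the interaction 12. Camera called 129 list shifts, and 0 with an estimated correlation.

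Calls went higher in 63.6% of cases for KP Smad4 against healthy, 50% with RLE scaling and 83.3% with the length offset, and the balance turned to 2 higher and 13 lower without the 4 libraries of lowest TMM factor. For KP Smad4 against KP the share was 21.4%, and 8.3% with the length offset, and for the interaction 100% and 79.6% with DESeq2. Some folds reversed. Without cerulein replicates 4, 6 and 7 Me1 was at −0.16, Pklr −1.04 and Dcn −0.44 in cerulein against healthy, and Me1 at 1.68, Pklr 1.49, Dcn 0.20 and Col3a1 0.08 in tumour against cerulein. With limma-voom Crispld2 was at 0.36 and Serpine1 at 1.10 in KP Cdkn2a against KP, Serpine1 at 0.03 in KP Smad4 against KP, and Arg1 at 3.49 and Stab1 at 0.05 in KP Cdkn2a Smad4 against KP. With DESeq2 Arg1 was at 0.90 and Rag1 at 0.75 there, and Serpine1 at 0.15 in KP Cdkn2a against KP.

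Leaving out 1 library at a time gave 810 to 1518 calls for tumour against healthy, 2213 to 3136 for cerulein against healthy and 2221 to 3760 for tumour against cerulein. Against healthy it gave 613 to 2136 for KP, 1364 to 2634 for KP Cdkn2a, 1 to 18 for KP Smad4 and 22 to 1072 for KP Cdkn2a Smad4. Against KP it gave 0 to 125 for KP Cdkn2a, 0 to 98 for KP Smad4 and 385 to 1614 for KP Cdkn2a Smad4, with 0 to 10 for the interaction and 754 to 1949 for any difference.

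With the replicate number as a block KP Smad4 had 6 calls against healthy, KP Cdkn2a 0 (Itgax and Fkbp5 included) and KP Smad4 3 against KP, and the interaction 0, while the other counts stayed within 1.5 times. Of 120 pairs of libraries with the same number 26 correlated above 0.1 (r from −0.38 to 0.39), and 9 of 48 libraries correlated best with their own number, so the numbers were not taken as pairing. Correlations over all genes do not rule out a shared effect on single genes, and 16 genes differed between numbers.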

Other observations

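All tests in this part were chosen after the results were seen, and the 7 gene lists added then are those used here.

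In KP against healthy blood 13 of 14 tissue macrophage genes were higher (edgeR, median 4.08), but 1 without KP replicate 1. Mast cell genes had 4 of 4 higher, and 3 without that library. Glucocorticoid target genes had 9 of 15 higher (median 0.85; camera adjusted p = 1.21e-06, and adjusted p = 0.0712 with an estimated correlation), and 5 without it. Thymocyte and lymphoid precursor genes had 3 of 10 higher, and 0 without KP replicate 2. In KP replicate 1, Arg1 stood at 514 CPM, Spp1 at 132, Serpine1 at 59.7 and the ductal keratin gene Krt19 at 7.17. KP replicate 2 had Rag1 at 137 CPM, Arpp21 at 28.9 and Dntt at 27.3. In KP replicates 1, 4 and 5, Fkbp5 stood at 64.5, 107 and 55.6 CPM, Crispld2 at 46.4, 39.2 and 21.7, and Il1r2 at 107, 44.0 and 34.9. The glucocorticoid target score was higher than in healthy blood by 0.91 in KP (exact permutation adjusted p = 0.0413, 7 of 8 mice) and 0.42 in cerulein blood (0.0245, 8 of 8). It was also higher in KP Cdkn2a (0.46, exact permutation adjusted p = 0.0254, 7 of 8), KP Smad4 (0.26, 0.0313, 8 of 8) and KP Cdkn2a Smad4 (0.33, 0.0245, 8 of 8).

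Liver macrophage and sinusoidal endothelium genes had 5 of 8 higher in cerulein than in healthy blood, with sums of 128, 172 and 108 CPM in cerulein replicates 4, 6 and 7. The sums were also 170 in KP replicate 1, 100 in KP replicate 2 and 98.0 in KP Cdkn2a Smad4 replicate 3, where hepatocyte sums were 2.03, 2.04 and 1.24, so they do not mark liver alone. The hepatocyte list had 2 members that passed the expression filter and were tested, and both were higher in cerulein blood. The rRNA-derived list had 2 of 2 lower in tumour than in healthy blood (median −4.94).

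The replicate numbers of the labels, tested as a factor beside the groups, differed in 16 genes (edgeR), among them the stress-responsive genes Sik1 (adjusted p = 0.000112), Tsc22d3 (0.000329), Cxcr4 (0.000368), Fosb (0.00159) and Dusp1 (0.0175). Of 26 shuffles of the numbers only the real one called as many, and the highest other called 4. That is the smallest share 26 shuffles can give, so it does not exclude chance. Among the 13 immediate early and heat shock genes not called here, 7 had an unadjusted p under 0.05. The real numbers alone (1 of 26) gave as many, and the highest other shuffle gave 4, though this list was picked for the test after its 2 called members were seen. Handling shared by libraries of 1 number, such as the time from bleeding to lysis, is a candidate explanation. With the TMM factor and the neutrophil and erythroid scores as covariates 20 genes were called, 11 of them among the 16, which argues against those 3 measures as the whole cause. The labels do not say what the numbers stand for.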
